A study of Mus musculus with 6 samples.

How the data were processed

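Gene expression was measured in intestinal epithelial cells of C57BL/6 mice on a 3′ Affymetrix expression array, from biotin-labelled cRNA made from total RNA, per the labels' protocols. Of the 6 arrays, 3 came from floxed control animals, which carry the floxed caspase-8 gene without the villin-Cre transgene. The other 3 came from animals with both, in which Cre recombinase under the villin promoter removes the floxed part of the gene in epithelial cells. Groups and replicate numbers were taken from the sample titles. The authors deposited the values as log2 expression made with RMA (robust multi-array average), per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a probe set; its version and settings are not given in the sources used here. The deposited log2 values ran from 1.13 to 14.1, with array medians between 4.85 and 4.91. RMA pulls dim signals towards a common floor, so that changes of dim genes are understated. The table holds no detection calls, so no gene could be called present or absent, and the number of arrays limits the precision.

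The table held 45101 probe sets, of which 64 were the manufacturer's control probe sets. By the platform annotation, which can be old, 34945 probe sets were paired with 1 gene, 932 with several and 9160 with none. Of those paired with 1 gene, 34737 were found in the RefSeq gene table, and 0 were renamed through their Entrez number. Probe sets with several genes or none were left out of the gene analysis. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays, which left 18193 genes. No filter on dim genes was applied. No genome build is named in the sources used here, and no coordinates are given.

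Deleted minus control was tested for each gene with limma 3.58.1 (lmFit and eBayes, two-sided, group as the only term) in R 4.3.3. The p-values were adjusted by Benjamini-Hochberg over the 18193 genes, with a threshold of 0.05. The fitted prior had 3.97 degrees of freedom and a standard deviation of 0.17. Values are given as mean ± SD over 3 arrays per group, and changes as log2 differences with their standard error (SE). The p-values measure the spread between arrays of separate animals, as the labels describe them. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

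Before the data were examined, 32 gene lists for cell types and pathways were fixed, with 823 entries in all, of which 738 were measured. Each list with at least 5 measured members was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 32 lists. Camera was also run with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. A rule for naming genes was fixed at the same time. It names Casp8, the 12 largest rises and 12 largest falls among genes that passed and whose groups did not overlap, and up to 4 members with the smallest p of each list. Genes with provisional names were skipped. Muc2, Pla2g2a, Mmp7 and Akr1b8 are named outside this rule, chosen after their values were seen, as are the kidney, sex-linked and NRF2 target genes of the closing section.

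The same steps were tested on simulated data for this comparison, with the 18193 genes and 200 of them changed, in 10 draws. Of genes changed by 1 on the log2 scale 69% were recovered, and of those changed by 2, 97.5%. On average 4.80% of calls were false. The goblet cell list, with each gene lowered by 1 on the log2 scale, was called in 100% of draws. Smaller shifts of a list were not simulated. Of the tests of unshifted lists, 0 of 280 were called. The genes were drawn independently of one another. These draws therefore cannot show how often unshifted lists are called when the genes of a list vary together.

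Alternatives fixed beforehand were the replicate number as a block, leaving out dim genes, the mean over a gene's probe sets, leaving out probe sets prone to cross-hybridisation, a variance trend with a robust prior, array weights, median centring, a repeated quantile normalisation, leaving out each array, a fold of at least 2, and testing single-gene probe sets separately. After the data had been seen, 2 settings on RNA integrity were added. The first takes each array's difference between the 3′ and the 5′ Gapdh control probe sets as a covariate, and the second leaves out control replicates 1 and 2. Further gene lists for other tissues, MHC class II and NRF2 targets were also written after the data had been seen and are used in the closing section alone.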

Results

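The series compared intestinal epithelial cells of 3 floxed control mice with those of 3 mice lacking caspase-8 in the gut epithelium, and asks what loss of the enzyme does to gene expression there. Caspase-8 is the protease that starts apoptosis from death receptors and holds necroptosis, a RIPK3-dependent form of cell death, in check. Each animal gave 1 array. Across the 18193 genes, the correlation between arrays was 0.990 to 0.994 among controls, 0.984 to 0.995 among deleted arrays and 0.979 to 0.991 between the groups. The 3′ minus 5′ difference of the Gapdh control probe sets, which rises as RNA degrades, was 0.68, 0.93 and 0.22 in control replicates 1, 2 and 3, and 0.29, 0.21 and 0.24 in the deleted replicates. The poly-A control transcripts, spiked into the RNA, averaged 8.97, 8.63 and 8.19 in the controls and 7.97, 7.84 and 7.28 in the deleted arrays on the log2 scale. Deleted replicate 1 held 211 genes that lay over 1 log2 unit above every other array, against 1 to 33 on each of the others.

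Without caspase-8, camera called the gene lists of Paneth and goblet cells lower, with 7 of 16 and 10 of 24 genes that fell, and those of the type I interferon response and wound repair higher, with 3 of 27 and 3 of 25 that rose. With an estimated correlation all 4 calls were lost, at adjusted p = 0.262 for Paneth cells, interferon and wound repair and adjusted p = 0.0716 for goblet cells. The angiogenin Ang4 of Paneth cells was 7.43-fold lower, and the mucin Muc2 of goblet cells 2.04-fold lower. Il1rn, which encodes the antagonist of the interleukin-1 receptor, was 9.95-fold higher by the probe set used, with log2 differences of 1.0 and 1.81 by its other probe sets, and the interferon-induced Ifit3 was 2.18-fold higher. In limma, 141 of 18193 genes passed an adjusted p of 0.05, of which 56 were higher and 85 lower in the deleted cells (n = 3 per group). Of these, 32 rose and 57 fell by at least 2-fold. In 4133 genes (22.7%) the groups did not overlap, where chance gives 10%, and all 141 genes that passed were among them. The median change of all genes was 0.022 on the log2 scale. The count lay between 18 (without deleted replicate 3) and 251 (without deleted replicate 1) when 1 array was left out, with 23, 31 and 56 without control replicates 1, 2 and 3 and 23 without deleted replicate 2. It was 5 without control replicates 1 and 2, the arrays with the highest Gapdh difference, and 36 with that difference as a covariate, both settings chosen after the data had been seen.

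Casp8 itself was measured by 1 probe set paired with that gene alone. It averaged 10.17 ± 0.40 in the controls and 9.74 ± 0.58 in the deleted cells (SD, n = 3). The log2 difference of −0.43 (SE 0.31, 95% confidence interval −1.13 to 0.28) did not pass (limma, adjusted p = 0.518). The arrays read 10.53, 9.74 and 10.24 in the controls and 9.27, 9.56 and 10.40 in the deleted replicates. The labels do not say which exons were removed, and a probe set outside them would still report the shortened transcript, so this value cannot check the genotypes.

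Among the 12 largest falls, Pla2g4c, a cytosolic phospholipase A2, dropped from 8.25 ± 0.67 to 4.25 ± 0.18 (log2 −4.00, SE 0.30, limma adjusted p = 0.00251). Clps, the colipase that anchors pancreatic lipase on fat droplets, dropped from 10.64 ± 0.17 to 7.46 ± 0.14 (9.07-fold lower, adjusted p = 0.00021). The mucosal pentraxin Mptx1 was 9.29-fold lower, the gasdermin Gsdmc2 5.78-fold lower and the stress-induced regulator Nupr1 5.06-fold lower. Bex4, Cd74, Itln1, Nrn1, Defa39 and Ceacam10 fell by 1.99 to 2.22 on the log2 scale, Ceacam10 least and Bex4 most. Ang4 fell by 2.89, and its second probe set stood at −3.34. The probe sets behind Ang4 and the alpha-defensin Defa39 are of a type that may bind close relatives, so their values may mix family members. Other probe sets of Pla2g4c, at −0.46, and Ceacam10, at −0.20, differed far less than the ones used, while another for Ceacam10 stood at −2.14.

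Il1rn led the rises, from 4.71 ± 0.35 to 8.02 ± 0.58 (log2 3.31, SE 0.30, limma adjusted p = 0.00457), and its mean over 3 probe sets was 2.04. Crct1 rose from 4.32 ± 0.06 to 7.50 ± 0.35, or 9.06-fold (adjusted p = 0.000962), and Anxa1, the anti-inflammatory annexin A1, was 7.66-fold higher (adjusted p = 0.0247). The Ly6 family genes Ly6g6c and Ly6d rose by 2.64 and 2.44 on the log2 scale. The glutathione S-transferases Gsta3 and Gsta2 and the carbonyl reductase Cbr3, all enzymes of detoxification, rose by 2.03, 1.74 and 1.71. Acta1, Sema3e, Paqr8 and Tm4sf4 rose by 2.09, 1.90, 1.76 and 1.69. The Acta1 probe set may also read other actins, and Gsta2 has near-identical relatives, so both remain uncertain. A second Anxa1 probe set stood at 0.49, the other 3 for Sema3e at 0.47 to 0.78, the others for Ly6g6c at 1.02 and 1.55 and a second for Gsta3 at 1.35. Of 47 named genes that passed, 12 did so without each array in turn, and 30, 30 and 21 lost the call without control replicates 1, 2 and 3. Without deleted replicates 1, 2 and 3 the call was lost by 1, 31 and 33.

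**Figure D1:**
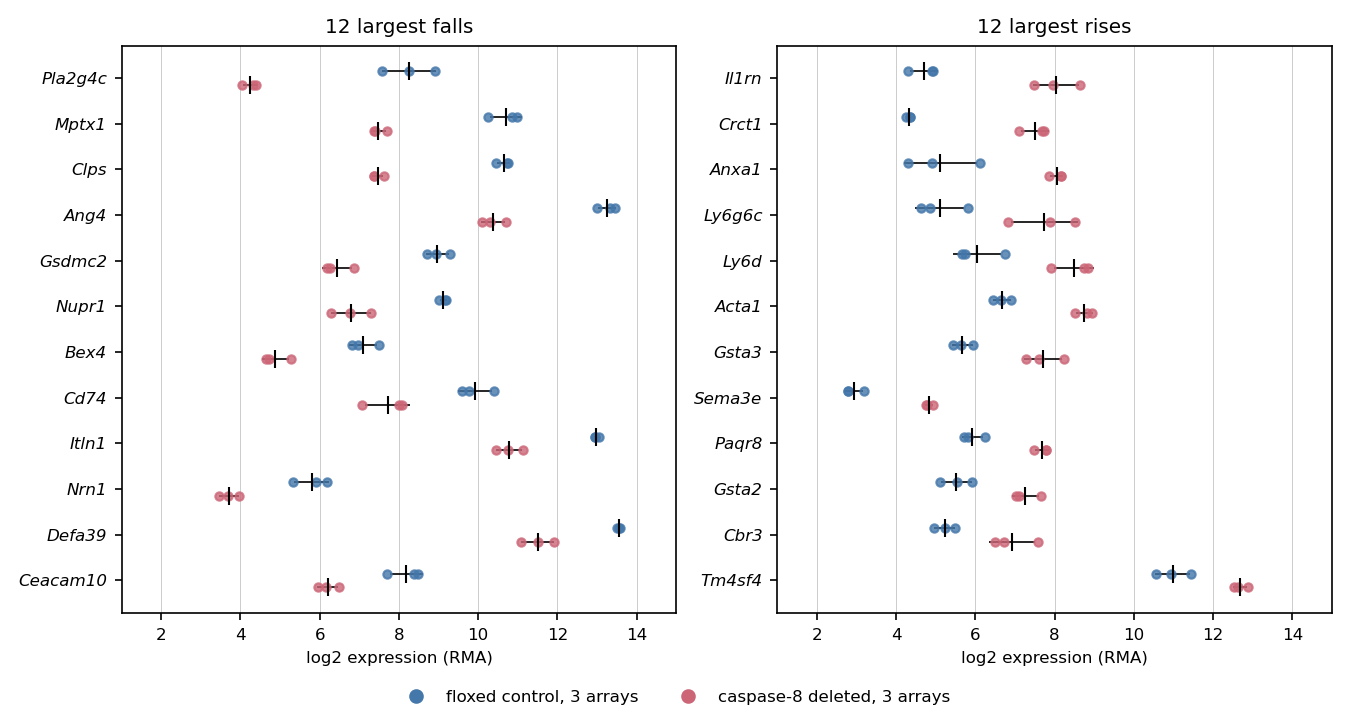
RMA log2 expression (horizontal axis) of the 12 genes with the largest falls (left) and the 12 with the largest rises (right), with 1 point per array, a black tick at the group mean and a bar of ± SD over 3 arrays. Clps averages 10.64 in the controls and 7.46 in the deleted cells, Crct1 4.32 and 7.50, and for each gene shown the groups do not overlap.

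Paneth cells, at the crypt base, secrete antimicrobial proteins, and goblet cells secrete mucus. Of 16 measured Paneth cell genes, 7 fell, 0 rose and 9 did not pass, with a mean change of −1.13 and a median of −0.53. Adjusted over the list alone, 10 fell. Itln1, an intelectin that binds microbial sugars, dropped from 12.98 ± 0.07 to 10.78 ± 0.34. Lyz1, which encodes lysozyme, fell by 1.33, the phospholipase Pla2g2a by 1.89 and Mmp7, the protease that activates defensins, by 1.82. Camera's adjusted p was 5.88e-13, and adjusted p = 0.262 with an estimated correlation. Of 24 goblet cell genes, 10 fell, 0 rose and 14 did not pass, with a mean of −0.78 and a median of −0.82. Adjusted over the list alone, 20 fell. The chemokine Ccl6 fell by 1.85 and the protease inhibitor Spink4 by 1.13, and Clca1, a secreted protein of mucus, was 2.14-fold lower. Atoh1, the transcription factor that commits cells to the secretory lineage, fell by 0.84 (camera adjusted p = 7.27e-21, adjusted p = 0.0716 with an estimated correlation). All 3 deleted arrays lay at or below −0.97 for the Paneth list and −0.73 for the goblet list, relative to the control mean. Control replicate 3, whose Gapdh difference matched the deleted arrays, stood at 0.14 and −0.022.

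The other secretory types had smaller mean changes. Of 24 enteroendocrine genes, 1 fell, 0 rose and 23 did not pass (mean −0.30), and adjusted over the list alone 3 fell. Gcg, which encodes the glucagon precursor, fell by 1.11, while Pyy stood at −0.72 and Tac1 at −0.65 (0.26 by its second probe set) without passing. The list's adjusted p by camera was 8.15e-06, and adjusted p = 0.0953 with an estimated correlation. Of 20 tuft cell genes, 0 passed and, adjusted over the list alone, 7 fell (mean −0.44). Spib and the tuft cell marker Dclk1 stood at −1.01 and −1.07, the other Dclk1 probe sets running from −0.98 to 0.15 (camera adjusted p = 1.42e-05, adjusted p = 0.417 with an estimated correlation). Control replicate 3 stood above the other controls for this list, at 0.34 against −0.26 and −0.086, and without it the mean was −0.27 (adjusted p = 0.000466).

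Of 22 stem cell genes, 2 fell, 0 rose and 20 did not pass (mean −0.48), and adjusted over the list alone 13 fell and 1 rose. Lgr5, the receptor that marks crypt base stem cells, fell from 7.33 ± 0.38 to 5.71 ± 0.50 (3.07-fold lower, limma adjusted p = 0.0488), and Sox9, a transcription factor of the crypt, fell by 0.87. A second Lgr5 probe set stood at −0.024, and with the mean of its probe sets Lgr5 was at −0.82 and did not pass (adjusted p = 0.0881). The other Sox9 probe sets stood at −0.86 and −0.36. For the stem cell list, camera gave adjusted p = 1.93e-07, and adjusted p = 0.262 with an estimated correlation. Of 37 cell cycle genes, 0 passed over all genes and 12 fell adjusted over the list alone (mean −0.41). The cyclin Ccnd1 stood at −1.08, Kif11 and Mcm6 each at −0.53 (camera adjusted p = 2.92e-13, adjusted p = 0.337 with an estimated correlation).

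Of 39 enterocyte genes, 1 rose, 0 fell and 38 did not pass (mean 0.26), and adjusted over the list alone 2 rose and 1 fell. Rbp2, the retinol-binding protein of enterocytes, rose by 0.97, while Treh stood at 0.58 and Mep1a at −0.87 without passing over all genes. For the enterocyte list, camera gave adjusted p = 2.45e-05, and adjusted p = 0.262 with an estimated correlation. Of 23 genes of PPAR signalling and fatty acid oxidation, 0 passed, also adjusted over the list alone (mean 0.35, camera adjusted p = 0.000298, adjusted p = 0.417 with an estimated correlation). Acadm and Creb3l3 stood at 0.44 and 0.57.

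Of 27 type I interferon response genes, 3 rose, 0 fell and 24 did not pass (mean 0.66), and adjusted over the list alone 17 rose. All 27 had a positive difference. Oas1a, which senses double-stranded RNA, rose by 0.94, Rtp4 by 1.13 and Ifit3 by 1.12, and Dhx58 stood at 0.87 without passing over all genes. Other probe sets stood at 0.51 for Rtp4 and at −0.093 and 0.059 for Dhx58. Camera's adjusted p was 3.85e-14, and adjusted p = 0.262 with an estimated correlation. Of 32 genes of the interferon gamma response and antigen presentation, 4 fell, 0 rose and 28 did not pass (mean −0.49), with 6 lower adjusted over the list alone. The 4 all serve MHC class II, which presents antigen to helper T cells. Cd74, its invariant chain, dropped from 9.92 ± 0.42 to 7.71 ± 0.56, and H2-Aa, H2-Ab1 and H2-Eb1 changed by −1.90, −1.79 and −1.58. Camera's adjusted p was 3.92e-05, and adjusted p = 0.622 with an estimated correlation. Without control replicate 2 the list's mean was −0.28 and its adjusted p 0.0551.

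Of 25 wound repair genes, 3 rose, 0 fell and 22 did not pass (mean 0.55, median 0.29), and adjusted over the list alone 6 rose and 1 fell. Il1rn, Anxa1 and Plaur, the urokinase receptor (0.77), were the 3, and Tnfrsf12a, the receptor of the cytokine TWEAK, stood at 1.15. Camera's adjusted p was 6.30e-05, and adjusted p = 0.262 with an estimated correlation. Of 37 genes of extrinsic cell death and necroptosis, 1 rose, 0 fell and 36 did not pass, with 5 higher and 1 lower adjusted over the list alone (mean 0.088, camera adjusted p = 0.255). The 1 that rose was Ripk3, the kinase of necroptosis, from 7.72 ± 0.01 to 8.55 ± 0.18 (limma adjusted p = 0.0365). Without deleted replicate 1 it still passed (adjusted p = 0.0272), and without each of the other 5 arrays in turn it did not (0.0875 to 0.162). Of 19 inflammasome and interleukin-1 family genes, Il1rn rose, Gsdmc2 fell and 17 did not pass (mean 0.17, camera adjusted p = 0.603), and adjusted over the list alone 3 rose and 1 fell. Of 36 genes of the NF-kB and TNF response, 0 passed, also adjusted over the list alone (camera adjusted p = 0.971).

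**Figure D2:**
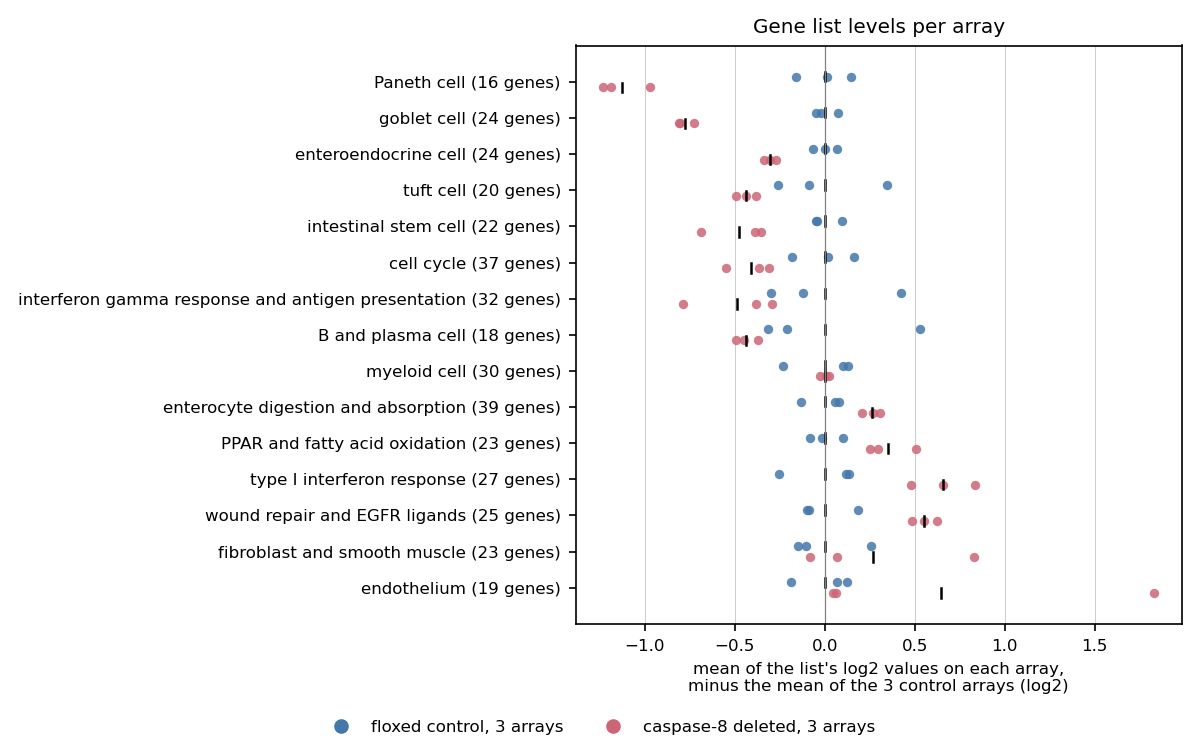
Mean of each gene list's log2 values on each array (points), minus the mean of the 3 control arrays, for 15 of the lists, with a black tick at each group's mean. The deleted arrays lie at −0.97, −1.23 and −1.19 for the Paneth cell list and at 0.48, 0.84 and 0.65 for type I interferon, and for endothelium deleted replicate 1 alone stands apart, at 1.83.

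Markers of other cells that a preparation of epithelium can hold were measured too. Of 19 endothelial genes 0 passed (mean 0.65), yet camera called the list (adjusted p = 0.00862, adjusted p = 0.633 with an estimated correlation). Deleted replicate 1 stood at 1.83 and the other deleted arrays at 0.064 and 0.048. Without it the mean was 0.056 and the adjusted p 0.695, and without control replicate 2 they were 0.55 and 0.0551. Of 23 fibroblast and smooth muscle genes 0 passed, with 1 higher adjusted over the list alone (mean 0.27, camera adjusted p = 0.0386, adjusted p = 0.622 with an estimated correlation). That call was lost without deleted replicate 1 (mean −0.0083, adjusted p = 0.665), control replicate 1 (0.20, 0.158) or control replicate 2 (0.22, 0.0788), and without deleted replicate 3 the mean was 0.45 (adjusted p = 0.00368). Of 18 B and plasma cell genes 0 passed (mean −0.44, camera adjusted p = 0.0101, adjusted p = 0.633 with an estimated correlation). Control replicate 3 had the highest level of them, and without it the mean was −0.17 and the adjusted p 0.216. Of 16 pancreatic acinar genes, Clps and the lipase-related Pnliprp1 (−1.20) fell and 14 did not pass, and adjusted over the list alone 4 fell and 2 rose (mean −0.35, camera adjusted p = 0.0386, adjusted p = 0.633 with an estimated correlation). That call was lost without control replicate 3 (−0.19, 0.686) or deleted replicate 1 (−0.38, 0.0688). The pancreatic list shares Rnase1 with the Paneth list and Zg16 with the goblet list, so it does not hold genes of pancreatic cells alone.

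Camera did not call the lists of 27 T cell, 30 myeloid, 12 mast cell and 8 red blood cell genes (adjusted p = 0.0726, 0.923, 0.923 and 0.923). Of the T cell and red blood cell genes 0 passed, also adjusted over the list alone. Of the myeloid genes, Lyz2 fell by 1.54 and Mrc1, a macrophage receptor, rose by 1.06, both also adjusted over the list alone. Lyz2 is nearly identical to the Paneth gene Lyz1, so its probe set may read both. Of the mast cell genes Kit fell by 0.86, also adjusted over the list alone, while its second probe set stood at −0.081. The T cell list was called without control replicate 1 (mean −0.32, adjusted p = 0.000119), deleted replicate 2 (−0.22, 0.019) or deleted replicate 3 (−0.27, 0.00627).

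Autophagy (19 genes, mean 0.14) and immediate early genes (22 genes, mean 0.16) were called higher by camera, at adjusted p = 0.0386 and 0.0478. With an estimated correlation these were adjusted p = 0.262 and 0.417, and 0 of their genes passed, also adjusted over the list alone. The unfolded protein response (26 genes, mean −0.096) and ileal bile acid handling (10 genes, mean −0.28) were called lower, at adjusted p = 0.0386 and 0.0413, with adjusted p = 0.418 and 0.491 with an estimated correlation. Of the former Ern2, a stress sensor of goblet cells, fell by 1.13, which was also the 1 gene adjusted over the list alone. Of the latter 0 passed, and 3 were lower adjusted over the list alone, with the hormone gene Fgf15 at −1.17. Each of these 4 calls was lost without deleted replicate 1, at adjusted p = 0.0943, 0.0943, 0.291 and 0.315, with means of −0.050 and −0.17 for the last pair, and without control replicate 3, at 0.14, 0.191, 0.0594 and 0.217. Without control replicate 1, autophagy, immediate early genes and the unfolded protein response stood at 0.0684, 0.0837 and 0.0768, and without deleted replicate 2 the former pair stood at 0.0515 and 0.142.

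Camera did not call regenerating and inducible defence (23 genes, mean −0.27, adjusted p = 0.0874), tight and adherens junctions (23 genes, mean 0.10, adjusted p = 0.104), Wnt and Notch signalling (27 genes, adjusted p = 0.551) or cholesterol synthesis (20 genes, adjusted p = 0.554). Nor did it call duodenal and jejunal (17 genes, mean 0.042, adjusted p = 0.492) or colonic genes (17 genes, mean −0.46, adjusted p = 0.104). In these 6 lists, 2 genes passed, Atoh1 and Ang4, which fell and belong also to the goblet and Paneth lists. Adjusted over the list alone, 1 duodenal gene rose and 2 fell, 1 colonic gene rose and 4 fell, and of the Wnt and Notch genes 1 fell, against 0 in the other 3 lists. Without control replicate 2 the defence list was called (mean −0.45, adjusted p = 0.000527), as was the cell death list (0.15, 0.018). The junction list was called without deleted replicate 3 (0.16, 0.0255). The mean, the median and camera's direction differed in sign for NF-kB, Wnt and Notch, cholesterol, myeloid and red blood cell genes. In all, camera called 19 of 32 lists, 8 higher and 11 lower, of which 10 kept the call without each array in turn. With an estimated correlation 0 of the 19 calls held, the lowest adjusted p being 0.0716 for goblet cells. By fry 9 lists passed, 8 of them also by camera, the other being the colonic list (fry adjusted p = 0.0184). The 8 were the Paneth, goblet, enteroendocrine, stem cell, enterocyte, type I interferon, wound repair and autophagy lists.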

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

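The tests of tissue, sex, labelling, RNA integrity, crypt bases, myeloid cells and B cells in this part, and the regrouping of the arrays, were chosen or worded after the results had been seen. No test for single outlying arrays was run within the groups of 3. The bootstrap intervals in this part resample the genes of a list, not the animals, and treat the genes as independent. They do not measure the spread between animals.

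Probe sets that the annotation pairs with no gene or with several genes were outside the gene analysis, and some were higher in the deleted arrays. Tested in limma over all 45037 probe sets other than controls, 3 of those with no gene were higher and 10 lower, and 1 of those with several genes was higher and 4 lower. Their identity was not analysed here.

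Splitting the 6 arrays into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split gave 141 genes and the highest of the others gave 0, so that 1 split had as many as the real one, itself.

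Deleted replicate 1 held 211 genes over 1 log2 unit above every other array, among them the kidney genes Umod (7.87, at most 3.55 elsewhere), Slc12a1 (7.77, at most 3.41) and Podxl (9.91, at most 5.06), named after their values were seen. A female animal is argued against, since the Y-linked genes Eif2s3y, Kdm5d and Uty lay a median −0.494 from the other arrays, although Xist read 6.97 against at most 4.48. A control animal under the wrong label is argued against, since its Paneth and goblet cell genes averaged −0.845 relative to the lowest control. RNA from kidney tissue, possibly of a female animal, stays open. Over 52 other kidney genes the array exceeded the mean of deleted replicates 2 and 3 by a median of 0.596 (95% bootstrap interval over genes, 0.27 to 0.93). For liver, lung and muscle genes the medians were 0.127, 0.115 and 0.195. The excess was over 1 log2 unit for 17 of the 52, against 0 of 18 liver, 1 of 15 lung and 0 of 17 muscle genes. Of these 52 genes, 8 averaged above 7 on the other arrays and 0 were in the 32 lists, and no biological explanation for a difference within the group was tested.

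The fall of Paneth and goblet cell genes was set against RNA integrity and the recovery of crypt bases. Degraded RNA in control replicates 1 and 2 as the whole cause is argued against by a fit over the 6 arrays with the Gapdh difference as a covariate, in which the genes of both lists averaged −0.948 (95% confidence interval −1.12 to −0.78), but much of this rests on control replicate 3: without it the value was −0.82 (−1.52 to −0.11), and the Paneth (−3.38 to 0.93) and goblet (−1.25 to 0.15) intervals each included 0. Fewer crypt bases would take stem cell genes down as much only if these were confined to the base, and not all of them are. Among genes with a control mean above 7 the Paneth mean was −1.70 (10 genes) and the stem mean −0.58 (16 genes). That gap was −1.12 (95% bootstrap interval over genes, −1.75 to −0.50). Over all members, dim ones included, the gap was −0.65 (−1.23 to −0.10) in the mean but 0.059 in the median. Lgr5 itself fell by 1.62 with the probe set used, though its second one stood at −0.024. With a stem list not confined to the base, the gap cannot decide, and fewer crypt bases stay open. A smaller contribution of degraded RNA stays open too. A loss of these secretory cells or of their transcripts after the deletion may also account for the fall, which was not tested. The different poly-A spike levels of the groups were not tested as a cause.

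Over 6 MHC class II genes, a set chosen after the data had been seen and not tested as a list, the mean difference was −1.64, and 4 of them fell while H2-DMa (−1.81, adjusted p = 0.0541) and Ciita (−0.53, adjusted p = 0.145) did not pass in limma. Fewer myeloid cells are argued against by the 5 myeloid genes other than Lyz2 with a control mean above 7. They averaged −0.177 (95% bootstrap interval over genes, −0.47 to 0.07), with Laptm5 (−0.73), the 1 outside the 32 lists, lowest. The 29 genes of the myeloid list without Lyz2 averaged 0.054 (−0.048 to 0.17), but most of them are dim, so this mean cannot decide. More B cells in the controls were examined with 15 B cell genes, leaving out Ighm, Igha and Jchain. Their mean lay within 0.3 of the deleted mean in control replicates 1 and 2, where MHC class II still stood at least 1.5 above its deleted mean. Yet in both arrays Ighm (8.11 and 8.13), Cd79b (5.81 and 5.75) and Pou2af1 (3.92 and 3.89) lay above every deleted array. Igha did so in control replicate 2 alone. Some of these genes are dim, so the comparison cannot decide and more B cells stay open. Lower expression in the epithelial cells themselves may be the cause and stays open and untested, as do fewer dendritic cells, whose genes Itgax (−0.24), Flt3 (−0.13) and Xcr1 (0.18) did not pass but were too dim to decide, with control means of 6.69, 5.70 and 3.11.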

How the results depend on the processing

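The 2 settings on RNA integrity were chosen after the data had been seen; all others were fixed beforehand. The count of 141 genes (56 higher, 85 lower) became 298 (131 and 167) with dim genes left out, where 9096 genes were tested, 252 (116 and 136) with a variance trend and robust prior, 1406 (702 and 704) with array weights, and 89 at a fold of at least 2 (32 higher, 57 lower). With the Gapdh difference as a covariate it was 36 (6 and 30), and without control replicates 1 and 2 it was 5 (0 and 5), in a fit with a lone control assumed to vary like the other group. Leaving out each array gave 18 to 251 genes (4 to 99 higher, 14 to 152 lower) and 12 to 21 lists called. With an estimated correlation 0 lists were called, and by fry 9. The cause was not tested, and a loss of power with fewer arrays cannot account for the rise to 251 genes without deleted replicate 1 or to 21 lists without deleted replicate 3. The replicate block gave 113 genes, 88 of them shared with the 141, and 17 lists. After the group means were removed, same-numbered samples correlated at 0.077, 0.105 and −0.007. Control replicates 1 and 2 matched their own number best and control replicate 3 did not, so the labels' numbers were not taken to pair the samples. Under the replicate block, autophagy, immediate early genes and the unfolded protein response lost the call and the T cell list gained it. Casp8 kept its direction and did not pass in any setting run, with −0.75 to −0.19 without each array. Lists that were not called, and the genes Cd2, Cpa3 and Fcer1a, turned direction, and the mean of the called fibroblast list turned to −0.0083 without deleted replicate 1, where its call was lost. For NF-kB the test turned at a mean of 0.011 with the replicate block and by fry, 0.039 without dim genes, 0.020 with mean probe sets and 0.14 with array weights, and −0.077 to 0.097 without each array. With array weights T cell genes were at 0.080 and myeloid genes at 0.13, and with repeated quantile normalisation myeloid genes were at 0.013. Without each array the lists ran from −0.12 to 0.067 (myeloid), −0.024 to 0.16 (mast cell), −0.17 to 0.082 (red blood cell) and −0.069 to 0.0089 (cholesterol). The means of the Wnt and Notch list (−0.10 to 0.044) and the duodenal list (−0.029 to 0.15) also crossed 0 without each array, while camera's direction held. With the Gapdh covariate Cd2 was −0.055, Cpa3 −0.19, Fcer1a −0.19, Wnt and Notch 0.056, mast cell −0.15, red blood cell −0.32 and duodenal genes −0.12. Without control replicates 1 and 2 Cd2 was −0.053, Cpa3 −0.32, Fcer1a −0.24, mast cell −0.19, red blood cell −0.39 and duodenal genes −0.17; the cause was not tested. No detection calls were available, so how far signal over background limits dim genes is unknown.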

Other observations

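The test of NRF2 target genes, and the choice of genes in this part, were made after the results had been seen. Some large differences did not pass, where arrays of the same group lay far apart. Retnlb, an inducible goblet cell protein, averaged 6.36 ± 1.87 in the controls and 3.61 ± 0.19 in the deleted cells, and Saa1, an acute-phase protein, 10.39 ± 1.38 and 7.55 ± 1.72 (SD, n = 3). Neither passed in limma, with adjusted p = 0.155 and 0.189.

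Gsta2, Gsta3, Cbr3 and Akr1b8 rose, the last by 1.62 and chosen after its value was seen, and all belong to genes that the oxidative stress regulator NRF2 can induce. A wider NRF2 response may therefore be present in the deleted cells. Of 27 other NRF2 target genes, 25 had a positive difference, with a mean of 0.401 (camera unadjusted p = 8.79e-08, and unadjusted p = 0.0171 with an estimated correlation, in limma). These p-values stand outside the adjustment over the 32 lists. The differences were uneven: Mt1 (1.49), Ces1g (1.03) and Mt2 (0.98) had the largest. Nqo1 (0.25), Gclc (−0.0055), Hmox1 (0.20) and Txnrd1 (0.18) differed little, so the mean does not hold for each target. With an estimated correlation, camera's unadjusted p was 0.00224 for goblet and 0.0287 for Paneth cells, whose calls were lost after adjustment. Of the 27 NRF2 target genes, 1 passed over all genes, Mt1, which was among the changed genes seen before the list was written and also responds to metals. Adjusted over the list alone 10 passed, and without Mt1 the mean was 0.36 and camera's unadjusted p 8.97e-07 at the preset correlation. The estimated correlation was not run without Mt1. NRF2 activity itself was not measured.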
